A study of soil metagenome with 120 samples.

How the data were processed

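DNA was extracted from 120 soil samples, 1.0 µg of it was labelled with Cy3 in a one-colour protocol, and each sample was hybridised to 1 GeoChip array, per the labels' protocols. The deposited file of each sample has 2 columns, a probe ID and a value; per the file headers no unit, scaling or background correction is stated, and scanner, image software and array layout are not given in the sources used here. The deposited values were treated as intensity, that is probe brightness on a linear scale, because the measured values run from 85.5 to 3.15e+06 with no negative value. Array totals lie within a narrow range (332.6 to 421.6, in units of 1e+06), and each array has its own lowest value (85.5 to 1218), so the values look filtered and scaled before deposit; that is read from the values and not from a statement of the authors.

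Every file has the same 161961 rows in the same order. The last 35298 rows (21.8%) are those after the last row with a missing value or a value of 5000 or more on any array. By that rule they have no missing value and lie below 5000 (lowest 0.00106). In digits and correlations they differ in kind from the others. They are written with a median of 15 digits where no earlier value has more than 10, and have correlations between arrays of -0.0188 to 0.0196. No row before them is without a value on all arrays. These rows were left out of the main results after the data were examined, and all rows together were run as an alternative. The 126663 earlier rows are called measured probes, and a missing value was read as a probe not listed on that array, not as 0.

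The files do not pair probe numbers with genes or organisms, and no array annotation was used here. The gene families, pathway lists, core genes and organism groups fixed before the data were examined could therefore not be tested as planned, and their tests are not analysed here. In their place stand 3 sets of probes whose IDs hold letters of a gene name (coxL, Hydrogenase and AssA), set after the IDs were seen; the letters hzo stand in 1 ID, which is among the last rows. The other IDs are numbers, some with a final letter.

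Each signal was divided by the total of the measured probes of its array and multiplied by 1e+06 (ppm); tests were run on log2 values. Single probes were tested over the 72327 probes listed on at least 60 of the 120 arrays, in one fit over the 3 biomes with lmFit, contrasts.fit and eBayes with a mean-variance trend (limma 3.58.1 in R 4.3.3), with Benjamini-Hochberg adjustment over probes and a threshold of 0.05. The 3 name sets were summed per array and fitted in the same way with the adjustment over the 3 sets of a comparison. With 3 rows this fit gives in effect 1 shared spread, so a permutation test was added. Listing was tested with Fisher's exact test per probe over probes listed on 5 to 75 of the 80 arrays of a comparison. Listed probes per array, the Shannon index (natural log) and distance to the biome's centre were compared by two-sided permutation tests of 100000 resamples with adjustment over the 3 pairs; the smallest p they can give is 1e-05. Composition was tested by PERMANOVA on Bray-Curtis dissimilarity with 99999 permutations, with the 3 pairs adjusted together. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used. Duplicate correlation was fitted with statmod 1.5.0.

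Named probes follow a rule fixed before the data were examined: for each comparison the 2 with the largest positive and the 2 with the largest negative log2 difference among probes past the threshold. Exceptions are iegcoxL63, the only probe with a gene name in its ID that passed, and iegcoxL90, which makes 1 array stand apart. A further exception is iegHydrogenase3, which held most of the signal of its set.

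The probe test was tested on simulated data for tropical minus temperate. Among 72327 simulated probes with 200 changed, it recovered 22% of changes of 0.5 and 94% of changes of 1 on the log2 scale, with 13 false calls. The listing test was tested on 20000 simulated probes of the same comparison with 200 raised by 40 percentage points, and recovered 36.5% with 3 false calls. The simulations did not test the effect of likeness between arrays with neighbouring sample numbers. When whole runs of the real arrays were exchanged, the highest count was 27517 by the probe test and 22290 by listing (median 0 for each). The simulated false calls and recovered shares are therefore not taken as error rate or power for the real arrays.

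Alternatives fixed before the data were examined were other scalings (75th percentile, quantile, none), other probe filters, removal of arrays over 3 MAD from the median of their biome (boreal samples 13 and 18), the sample number as a block, other dissimilarities, thinning, a count of listed probes above 1809.6 units only, and Bonferroni adjustment. Alternatives added afterwards treat runs of 4 consecutive sample numbers as units or blocks (30 runs, each within 1 biome), add the position in the run or the number of listed probes as a covariate, test listing above 1809.6 units, leave out 1 array, or use the permutation test for the name sets. That cut-off is the highest of the 5th percentiles of the arrays. The labels give no slide, scan or date, so runs of 4 stand in for a batch only as a reading of the data.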

Results

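Soil DNA from 3 biomes was hybridised to GeoChip, a microarray whose oligonucleotide probes target functional genes of soil microorganisms. The sample labels name urban park green space as the source while the design text speaks of forest soils, and the sources used here do not settle which holds. The series holds 120 arrays, with 40 from the boreal biome (Lahti, Finland), 40 from the temperate biome (Baltimore, USA) and 40 from the tropical biome (Singapore). Each array stands for 1 sampling site, at which about 0.10 kg of soil was taken down to 50 cm. Each biome was sampled in 1 city, so biome and city cannot be told apart in any comparison. The design text also names the age and the vegetation of the sites as factors, but the labels give neither for single samples, and no comparison on them was made. The labels name 120 separate soil samples from 3 cities. Unless runs are named, the p-values treat the arrays of these samples as independent. Runs of 4 consecutive sample numbers accounted for 46.4% of the variation, where 24.4% is expected with no grouping. P-values over single arrays may therefore be too small, and those over runs are given beside them where they were computed.

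Every array reported the same 126663 probes, and a probe without a value on an array is called not listed there. Boreal arrays listed 69010 ± 15135 probes (SD, n = 40), temperate arrays 75866 ± 12054 (n = 40) and tropical arrays 72208 ± 9034 (n = 40). The total signal of an array, in units of 1e+06, was 388.9 ± 21.9 in boreal, 397.2 ± 12.7 in temperate and 390.4 ± 17.7 in tropical arrays (SD, n = 40 each). Across the 120 arrays the listed probes ranged from 36611 on a boreal array to 96494 on a temperate array. The number of arrays limits the precision of every value below. No pair of arrays held identical values, and the most similar pair, temperate samples 5 and 6, had a Bray-Curtis dissimilarity of 0.0888.

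**Figure D1:**
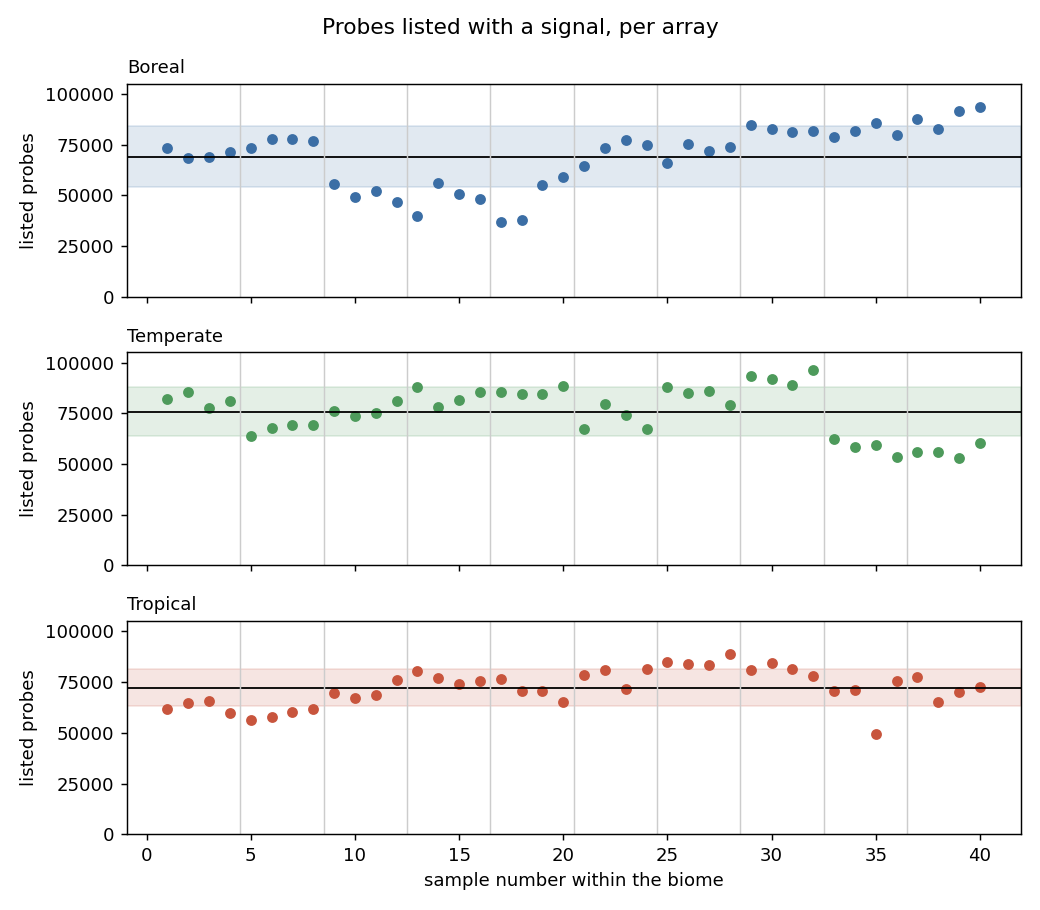
Number of probes listed with a signal (vertical axis) on each array against the sample number within its biome (horizontal axis), with the mean of the biome as a line, 1 SD either side as a band and grey lines between runs of 4 sample numbers. Boreal arrays spread from 36611 to 93437 listed probes, temperate arrays from 53026 to 96494 and tropical arrays from 49480 to 88929. Differences between runs hold 90.4%, 93.0% and 76.1% of the variance in boreal, temperate and tropical arrays.

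The first question was whether the 3 biomes differ in how many functional gene probes their soils light up. Temperate arrays listed 6856 more probes than boreal arrays, a difference that did not pass the adjusted threshold (permutation test, two-sided, p = 0.0274, adjusted p = 0.0821 over 3 pairs). The tropical minus temperate difference was -3658 probes (adjusted p = 0.191) and the tropical minus boreal difference 3198 probes (adjusted p = 0.253). Over means of runs of 4 the temperate minus boreal p was 0.269, and the adjusted p was 0.558 for each pair (permutation test). When only signals above 1809.6 units were counted on every array, the temperate minus boreal difference was -57.0 probes and the tropical minus boreal difference was -113.3 probes (adjusted p = 0.945 for both). The counts were then 41478 ± 4190 in boreal, 41421 ± 3205 in temperate and 41365 ± 3686 in tropical arrays (SD). These differences lie far within the spread and show no direction. The cut also removed a large part of the listed probes. The Shannon index of the relative probe signals was 10.23 ± 0.28 in boreal, 10.29 ± 0.20 in temperate and 10.29 ± 0.17 in tropical arrays (SD, n = 40 each). None of the 3 differences passed (adjusted p = 0.323, 0.323 and 0.996 for temperate against boreal, tropical against boreal and tropical against temperate). With every array thinned to 36611 probes, the index was 0.0444 higher in tropical than in temperate arrays (adjusted p = 0.0187). That test treats arrays as independent, and the thinned index was not tested over means of runs.

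Most probes were shared between biomes. Of the 126663 probes, 101453 (80.1%) were listed in all 3 biomes and 22448 (17.7%) on all 120 arrays. Probes seen in a single biome numbered 7928 in temperate, 3528 in boreal and 3175 in tropical arrays. Of these, 5851, 2936 and 2787 were listed on 1 array only, and 152, 23 and 19 were listed on at least 5 arrays.

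Community composition differed between biomes by a small share of the variation between arrays. Biome accounted for 3.73% of the variation in Bray-Curtis dissimilarity of relative probe signals (PERMANOVA, permutation p = 0.00355). The share was 2.98% for tropical against temperate, 2.60% for tropical against boreal and 2.90% for temperate against boreal arrays (adjusted p = 0.0306 for each). With Jaccard dissimilarity of presence and absence the 3 shares were 2.83%, 3.37% and 4.21% and none passed (adjusted p = 0.0589, 0.0507 and 0.0507). Over all 3 biomes the Jaccard share was 4.69% (PERMANOVA, p = 0.0087). With Euclidean distance of centred log2 signals the share passed over all 3 biomes (PERMANOVA, p = 0.00517) and for each pair (adjusted p = 0.0309). Arrays of different biomes had a mean dissimilarity of 0.266 ± 0.071 (SD), against 0.288 ± 0.074 within boreal, 0.247 ± 0.067 within temperate and 0.249 ± 0.066 within tropical arrays. Boreal arrays lay farther from the centre of their biome (0.2002 ± 0.056) than temperate (0.172 ± 0.050) and tropical arrays (0.174 ± 0.046; SD, n = 40 each; permutation test, adjusted p = 0.0339 for both). PERMANOVA also responds to such unequal spread. The 30 runs of 4 consecutive sample numbers, 10 in each biome, accounted for 46.4% of the variation, where 24.4% is expected with no grouping. When whole runs were exchanged between biomes, a biome share as large arose with p = 0.277, and for the dispersion the adjusted p over means of runs was 0.247 in both comparisons with boreal.

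**Figure D2:**
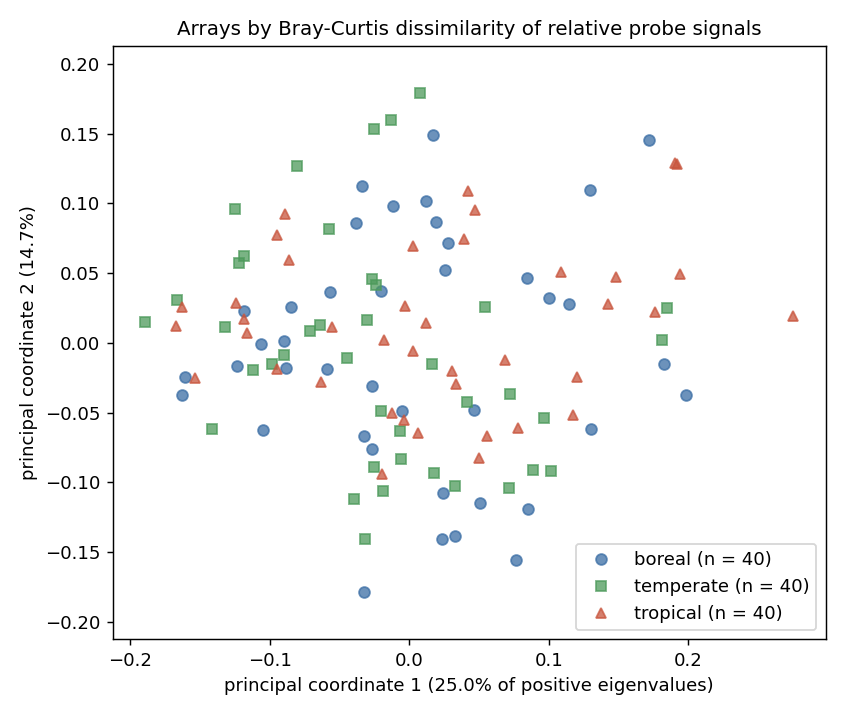
Principal coordinates of the 120 arrays from the Bray-Curtis dissimilarity of relative probe signals, 1 point per array, with 40 arrays in each biome; the horizontal and vertical axes hold 25.0% and 14.7% of the sum of positive eigenvalues. The 3 biomes overlap over most of the plot, where biome accounts for 3.73% of the variation.

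**Figure D3:**
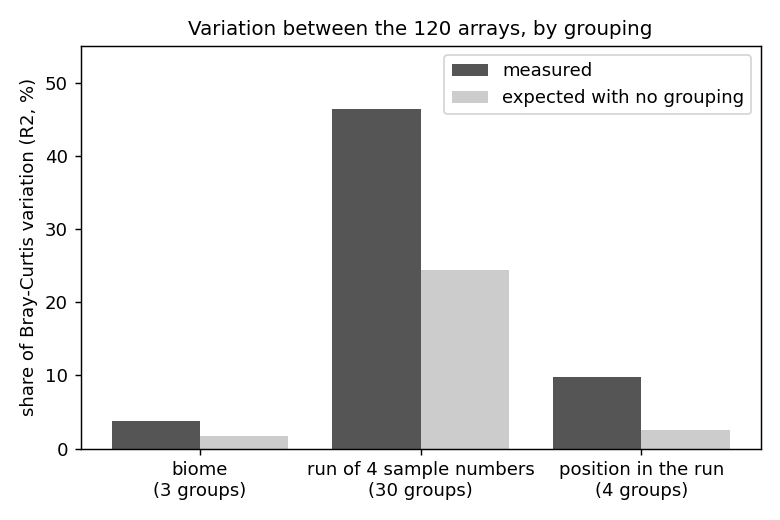
Share of the variation in Bray-Curtis dissimilarity (R2 in percent, vertical axis) accounted for by biome, by runs of 4 consecutive sample numbers and by position within a run, beside the share expected with no grouping. Runs account for 46.4%, position for 9.75% and biome for 3.73%.

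The files give probe numbers and do not pair them with genes, so the probes named next are given by number. A log2 difference or median of a probe covers only the arrays that list it; arrays that do not list it are left out, so where few do, the value does not describe the whole biome. Apart from these numbers, 50 measured probes have IDs that hold the letters of a gene name, namely 22 with coxL, 13 with Hydrogenase and 15 with AssA. Background for these names is that coxL is the usual symbol for the large subunit of aerobic carbon monoxide dehydrogenase. Hydrogenases are enzymes that oxidise or produce molecular hydrogen, and AssA denotes the alpha subunit of alkylsuccinate synthase, which activates alkanes without oxygen. That each probe targets the gene of its letters is read from the ID alone.

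Tropical against temperate soils compares the sites in Singapore with those in Baltimore. Among 72327 probes listed on at least 60 arrays, 695 differed (limma, adjusted p under 0.05), 254 higher and 441 lower in tropical arrays. The median size of these differences was 0.66 on the log2 scale, and 8.20% of them were over 1. Probe 92393560a had 24.5 ± 28.6 ppm (signal over the array total, times 1e+06) in tropical arrays (SD, 34 of 40 arrays) and 2.04 ± 0.68 in temperate arrays (33 of 40), a log2 difference of 2.46 ± 0.31 (SE, limma adjusted p = 4.35e-08). In 28 of the 34 tropical arrays that listed it, it lay above the temperate median. Probe 296119086 was higher in tropical arrays by 2.01 ± 0.29 (log2, SE, limma adjusted p = 1.28e-05), with 25 of the 28 tropical arrays that list it above the median of the 19 of 40 temperate arrays that do. Probe 333443217 was lower in tropical than in temperate arrays that list it, with a log2 difference of -2.16 ± 0.37 (SE, limma adjusted p = 0.000173), and 31 of 33 such temperate arrays lay above the median of the 17 of 40 tropical arrays that do. Probe 308162107a had 69.2 ± 100.8 ppm in temperate and 11.8 ± 12.5 in tropical arrays (SD, n = 40 and 39; log2 difference -1.84 ± 0.29 SE, limma adjusted p = 1.33e-05), with 31 of 40 temperate arrays above the tropical median.

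The Hydrogenase probes together held 203 ± 45 ppm of the signal in tropical arrays and 242 ± 89 in temperate arrays (SD, n = 40 each). Their log2 difference of -0.20 ± 0.09 (SE) did not pass (limma adjusted p = 0.0528), and 13 of 40 tropical arrays lay above the temperate median. With the 75th percentile, quantile or no scaling it passed, at -0.30, -0.22 and -0.23 (adjusted p = 0.00233, 0.033 and 0.0209). It also passed with the sample number as a block (adjusted p = 0.043) but not over means of runs (adjusted p = 0.162) or by permutation test (adjusted p = 0.0593), while the mean of the log2 signals of listed probes gave 0.04. Probe iegHydrogenase3 alone held 148 ± 49 ppm in tropical, 193 ± 93 in temperate and 169 ± 62 in boreal arrays (SD, n = 40 each). The Hydrogenase sum in each biome therefore mostly follows this probe. Its tropical minus temperate log2 difference was -0.31 ± 0.12 (SE, limma adjusted p = 0.221 over all probes). The median over the 9 Hydrogenase probes tested was -0.05. The coxL probes held 293 ± 412 ppm in tropical and 219 ± 20 in temperate arrays (log2 difference 0.15 ± 0.09 SE, adjusted p = 0.128; permutation test, adjusted p = 0.0593). Tropical sample 6 alone held 2829 ppm, of which 2631 came from probe iegcoxL90; the next highest array held 307. Without that sample the coxL difference was 0.06 (adjusted p = 0.149), and with 75th percentile and quantile scaling it was 0.05 each (adjusted p = 0.53 and 0.541). The AssA probes held 31.7 ± 7.4 and 32.0 ± 6.0 ppm (log2 difference -0.04 ± 0.08 SE, adjusted p = 0.637), with the opposite sign (0.13) from the mean of log2 signals. With adjustment over all 72327 probes, 0 of the 17 coxL, 9 Hydrogenase and 6 AssA probes tested passed. Adjusted over the list alone, 1 coxL probe was higher and 0 of the others passed, where the lists were formed after the IDs were seen.

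By listing, 364 of 51494 probes on 5 to 75 of the 80 arrays differed (Fisher's exact test, adjusted p under 0.05). Of these, 12 were listed more often in tropical and 352 more often in temperate arrays. Above 1809.6 units 75 differed, split 28 and 47, and only 11 of them were among the 364 with the same direction. Quantile normalization took the median log2 difference of all probes from -0.00280 to -0.12 and gave 1131 differing probes, 72 higher and 1059 lower in tropical arrays. With runs of 4 as a random block, 59 of the 695 probes passed.

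Tropical against boreal soils compares the sites in Singapore with those in Lahti. Here 1471 of 72327 probes differed, 400 higher and 1071 lower in tropical arrays, with a median size of 0.63 on the log2 scale and 5.03% over 1. The largest difference among the 3 comparisons was that of probe 157319312. It held 565 ± 1064 ppm in boreal arrays (SD, 38 of 40 arrays) and 3.13 ± 1.30 in tropical arrays (36 of 40), which is 36.4-fold in geometric means (log2 difference -5.18 ± 0.48 SE, limma adjusted p = 4.74e-15). All 38 boreal arrays that listed it lay above the tropical median, and 29 of them, from 10 of the 10 boreal runs, lay above every tropical array. Probe 189184923 held 33.4 ± 36.9 ppm in boreal and 7.08 ± 4.65 in tropical arrays (SD, n = 40 each; log2 difference -1.96 ± 0.20 SE, limma adjusted p = 7.33e-13), with 40 of 40 boreal arrays above the tropical median. Probes 296119086 and 92393560a were higher in tropical than in boreal arrays too, by 2.09 ± 0.33 and 2.06 ± 0.33 (log2, SE; limma adjusted p = 3.61e-05 and 1.84e-05), with 26 of 28 and 28 of 34 listing tropical arrays above the boreal median. Only 13 and 25 of 40 boreal arrays list these probes.

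**Figure D4:**
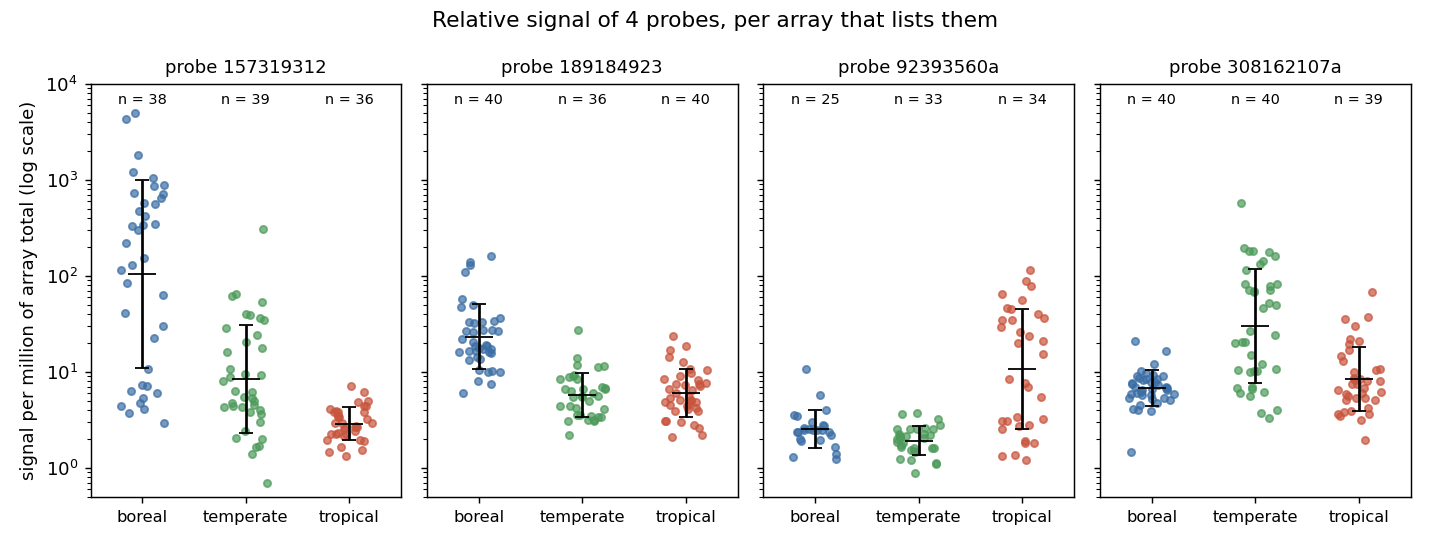
Relative signal of 4 probes (ppm of the array total, log scale) on each array that lists them, by biome, with the geometric mean and 1 SD of the log2 values as bars and the number of arrays above each group. Probe 157319312 has an arithmetic mean of 565 ppm in boreal arrays against 3.13 in tropical arrays, which is 36.4-fold in the geometric means drawn. Probe 92393560a has an arithmetic mean of 24.5 in tropical arrays against 2.04 in temperate arrays, 5.51-fold in geometric means.

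The coxL probes were the only name group that passed in this comparison. Tropical arrays held 293 ± 412 and boreal arrays 208 ± 24 ppm (SD, n = 40 each), with medians of 229 and 206. The log2 difference was 0.22 ± 0.09 (SE, limma adjusted p = 0.0304), and 33 of 40 tropical arrays lay above the boreal median. The permutation test gave an adjusted p of 0.00099. Without tropical sample 6 it was 0.13 ± 0.03 (adjusted p = 0.000646). The call ended with only the 80 arrays in the fit (adjusted p = 0.0664) and over means of runs of 4 (adjusted p = 0.112), and the sign turned with the mean of log2 signals of listed probes (-0.06). With adjustment over all 72327 probes, 0 of the 17 coxL, 9 Hydrogenase and 6 AssA probes passed. Adjusted over the list alone, 1 coxL probe was higher and 1 AssA probe lower in tropical arrays, with the lists again formed after the IDs were seen. The Hydrogenase probes held 203 ± 45 and 218 ± 54 ppm (log2 difference -0.09 ± 0.09 SE, adjusted p = 0.4), and the mean of log2 signals gave -0.34 (adjusted p = 0.00272). The AssA probes held 31.7 ± 7.4 and 33.3 ± 8.7 (log2 difference -0.07 ± 0.08 SE, adjusted p = 0.401); quantile and 75th percentile scaling turned that sign (0.09 and 0.02).

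By listing, 354 of 56976 probes differed (Fisher's exact test), 315 more often listed in tropical and 39 more often in boreal arrays. Above 1809.6 units 125 differed, split 44 and 81, and only 15 of them were among the 354 with the same direction. Quantile normalization gave 1609 differing probes with the split turned, 1125 higher and 484 lower in tropical arrays. With runs of 4 as a random block, 110 of the 1471 probes passed.

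Temperate against boreal soils gave the largest number of differing probes of the 3 comparisons. There were 5137 of 72327, 1286 higher and 3851 lower in temperate arrays, with a median size of 0.60 on the log2 scale and 4.56% over 1. Boreal arrays listed fewer probes than temperate arrays, and their lowest signal was higher (406 ± 225 against 321 ± 169 units, SD). Weak signals left out may thus raise boreal means. Among probes listed on all 120 arrays the split was the other way, 427 higher and 318 lower, so the split is not read as a direction of the soils. Probe 308162107a held 69.2 ± 100.8 ppm in temperate and 7.39 ± 3.34 in boreal arrays (SD, n = 40 each; log2 difference 2.15 ± 0.29 SE, limma adjusted p = 1.05e-07), with 33 of 40 temperate arrays above the boreal median. Probe 57016642 was higher by 2.04 ± 0.36 (log2, SE, limma adjusted p = 0.000142), with 30 of the 37 temperate arrays that list it above the median of the 21 of 40 boreal arrays that do. Probe 157319312 had 565 ± 1064 ppm in boreal and 22.3 ± 49.9 in temperate arrays (SD, n = 38 and 39; log2 difference -3.63 ± 0.47 SE, limma adjusted p = 5.38e-08), with 31 of 38 boreal arrays above the temperate median. Its medians were 187 ppm in boreal and 6.21 in temperate arrays, well below these means. Probe 189184923 fell by 2.01 on the log2 scale from boreal to temperate arrays (SE 0.21, limma adjusted p = 1.78e-12), and 40 of 40 boreal arrays lay above the temperate median.

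Probe iegcoxL63 was the 1 probe with a gene name in its ID that passed over all probes in any comparison, and it was chosen for mention after its values were seen. It held 17.0 ± 6.3 ppm in temperate (SD, n = 38) and 11.9 ± 4.5 in boreal arrays (n = 40), a log2 difference of 0.53 ± 0.12 (SE, limma adjusted p = 0.00207), with 33 of 38 temperate arrays above the boreal median. Over means of runs of 4 its adjusted p was 0.162. Summed by name, coxL held 219 ± 20 and 208 ± 24 ppm (SD, n = 40 each; log2 difference 0.07 ± 0.09 SE, adjusted p = 0.587). That SE is shared over the 3 biomes, and without tropical sample 6 it was 0.03 (adjusted p = 0.0957; permutation test on all arrays of the pair, adjusted p = 0.102). Hydrogenase held 242 ± 89 and 218 ± 54 (0.11 ± 0.09, adjusted p = 0.587), and AssA 32.0 ± 6.0 and 33.3 ± 8.7 (-0.03 ± 0.08, adjusted p = 0.712). With quantile scaling coxL and Hydrogenase passed as higher in temperate arrays (0.24 and 0.21, adjusted p = 0.0196 and 0.0262), and with the mean of log2 signals all 3 groups passed as lower (-0.14, -0.38 and -0.26, adjusted p = 0.0397, 0.000621 and 0.00671). That mean covers only the probes an array lists, so listing more weak probes lowers it. Temperate arrays listed a mean of 16.55 coxL, 9.5 Hydrogenase and 6.73 AssA probes, against 15.75, 8.3 and 6.2 in boreal arrays. The lower means are therefore not read as less signal of these sets.

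By listing, 1027 of 61283 probes differed (Fisher's exact test), 1023 more often listed in temperate and 4 more often in boreal arrays. Above 1809.6 units 50 differed, split 29 and 21, and only 11 of them were among the 1027 with the same direction. Quantile normalization took the median log2 difference of all probes from -0.06 to 0.15 and turned the split of the 7749 differing probes to 6843 higher and 906 lower in temperate arrays, and among probes listed on all 120 arrays 427 were higher and 318 lower. With runs of 4 as a random block, 516 of the 5137 probes passed, 125 higher and 391 lower.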

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

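The tests on the rows at the end of the files were chosen after those rows were seen. The last 35298 rows of every file hold values on every array that belong to no comparison above. That they hold a value on all 120 arrays follows from the rule that set them apart. Against a uniform distribution from 0 to 5000, 5.10% of the rows had a Kolmogorov-Smirnov p under 0.05, close to the 5% that uniform values give, and the mean was 2501 with an SD of 1444 (2500 and 1443 for a uniform distribution). Weak but measured signals would correlate between arrays, and the highest correlation of any 2 arrays was 0.0196, against a median of 0.799 for probes listed on all arrays, which argues against them. Random numbers placed where no array had a value are a candidate explanation that these values allow; no biological explanation was tested.

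Probe counts were compared with those from other splits of the same 80 arrays, 100 splits in each case with the real one included. The splits of arrays and of whole runs for probes, like those rows, were chosen after the results were seen; the splits of run means and of listing were written down before they were run. For splits of single arrays, as many differing probes arose in 1, 2 and 1 of the 100 splits for tropical minus temperate, tropical minus boreal and temperate minus boreal, where the real counts were 695, 1471 and 5137 and the highest other counts were 0, 11302 and 145. In the comparisons with temperate only the real split reached its count. For tropical minus boreal, 2 of 100 is too close to a share of 5% to set the real split apart with 100 splits. For listing, as many differing probes arose in 1 of 100 splits of single arrays in each comparison, with real counts of 364, 354 and 1027 and highest others of 1, 4 and 0. Exchanging single arrays treats them as independent, which their likeness within runs goes against. These splits therefore cannot exclude chance. When whole runs of 4 were exchanged, as many probes arose in 14, 15 and 20 of 100 splits (highest others 27517, 32259 and 22574), and for listing in 22, 14 and 23 (highest others 22290, 23501 and 31761). Chance is not excluded at that level. The larger share of such splits than for single arrays goes with a structure of the arrays along the runs. The highest counts alone do not show it, since 11302 also arose when single arrays were exchanged. With each run reduced to its mean, the real counts of 50, 93 and 356 were reached in 4, 2 and 2 of 100 splits (highest others 32409, 906 and 1328). With 100 splits, neither 4 nor 2 of 100 can be separated from a share of 5%, so chance is not taken as excluded in any of the 3 comparisons.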

How the results depend on the processing

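Settings over runs of 4, over positions, with the number of listed probes, with all rows of the files, above a common signal for listing, without 1 array, and the permutation test of the name sets were chosen after seeing the data. The 7 numbered probes named above kept direction and threshold in every comparison they were named for under each alternative that tested them, and of 130 such results 128 were unchanged, the other 2 being iegcoxL63. Its log2 difference stayed at 0.53 but did not pass with position and run block (adjusted p = 0.0611) or over run means (0.162). The 7 numbered probes were picked as the largest passing differences in these same arrays, so their staying past the threshold was likely beforehand. In comparisons they passed without being named for, 57016642 passed in 7 of 10 alternatives (tropical minus temperate). There 333443217 passed in 9 of 10 (temperate minus boreal). The cause was not tested for any change below unless stated.

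Counts of differing probes are given in the order tropical minus temperate, tropical minus boreal, temperate minus boreal. They were 1131, 1609 and 7749 with quantile scaling and 225, 459 and 745 over the fewer probes on all 120 arrays. They were 467, 919 and 3511 with all rows, 968, 2356 and 6020 with position as covariate and 728, 2246 and 5190 with the number of listed probes. They fell to 59, 110 and 516 with the run as random block (correlation within runs 0.203), 49, 103 and 272 with position as well, and 50, 93 and 356 over run means, where fewer units are compared. Of the main counts of 695, 1471 and 5137, only 511, 858 and 2190 also passed with quantile scaling, against 647, 1438 and 4695 with no scaling. No probe of the main counts that passed under an alternative had the opposite sign. A probe that must pass in each fit of the same arrays is unlikely to turn its sign. The absence of turned signs therefore does not show that the directions are stable. Counts by listing were 471, 643 and 1604 over probes on 10 to 70 arrays, 35, 17 and 45 with Bonferroni adjustment and 75, 125 and 50 above the common signal. Of those above the common signal, only 11, 15 and 11 were main calls with the same direction.

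Listed probes differed by -113.3 (tropical minus boreal) and -57.0 (temperate minus boreal) above the common signal. Thinning gave Shannon differences of 0.0444 (tropical minus temperate) and -0.0374 (temperate minus boreal, adjusted p = 0.161). Dispersion from Jaccard dissimilarity differed by -0.0229 for tropical minus temperate (adjusted p = 0.0323). Over run means the dispersion differences of -0.0262 and -0.0286 against boreal did not pass (adjusted p = 0.247). The Jaccard shares for the 3 pairs were 2.83%, 3.37% and 4.21% (adjusted p = 0.0589, 0.0507 and 0.0507). With whole runs exchanged, the shares of 3.73% overall and 2.98%, 2.60% and 2.90% did not pass (p = 0.277, adjusted p = 0.304 for each pair).

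Name sets past the threshold numbered 0, 1 and 0. For tropical minus temperate 1 set, Hydrogenase, passed with 75th percentile, quantile and no scaling and with the replicate block. For tropical minus boreal 0 passed with only the 80 arrays or over run means. For temperate minus boreal 2 passed with 75th percentile and quantile scaling and 3 with the mean of log2 signals. That mean turned the sign of Hydrogenase (0.0424) and AssA (0.13) for tropical minus temperate, of coxL (-0.0640) for tropical minus boreal, and of coxL (-0.14) and Hydrogenase (-0.38) for temperate minus boreal. It covers only listed probes, so it also moves with how many weak probes an array lists. AssA turned to 0.0164 and 0.0908 for tropical minus boreal with 75th percentile and quantile scaling, and to 0.15, 0.23 and 0.00337 for temperate minus boreal with these and no scaling.

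Sample numbers paired samples across biomes weakly at most. Same-numbered arrays deviated together with mean correlations of 0.0870, 0.0210 and 0.0828 in the 3 pairs. For other numbers the means were -0.000907, 0.000597 and -0.000355. Lowest values for the same number were -0.494, -0.642 and -0.410 and highest values 0.587, 0.512 and 0.713. In the 3 pairs 2, 0 and 1 of 40 arrays correlated best with their own number. Same-numbered arrays also share their position in the run, so pairing and position cannot be told apart here. With the replicate block the counts of differing probes were 1184, 3118 and 6321, and the biome share of 3.73% had p = 0.00156. Planned settings on gene lists, on families in composition, diversity and dispersion, and on organism groups were not run because no annotation pairs the probes with genes or organisms; the slide block was not run because no source gives slides, and the minimum of 5 probes removed none of the 3 sets.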

Other observations

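The tests of position and the correlation of listed probes with the lowest signal were chosen after the result was seen; the boundary, final-letter and common-signal tests were written down before they were run. Arrays with neighbouring sample numbers were alike: arrays of 1 run of 4 had a mean Bray-Curtis dissimilarity of 0.218 ± 0.075 (SD), arrays of different runs of 1 biome 0.265 ± 0.070 and arrays of different biomes 0.266 ± 0.071. Adjacent numbers across a run boundary differed more than the first and last array of 1 run, by 0.0265, but not beyond the permutation test (27 and 30 pairs, p = 0.119), so sets of 4 arrays processed together and neighbouring sites cannot be told apart. Position within the run accounted for 9.75% of the variation (2.52% expected, permutation p = 0.0001, the smallest that its permutations can give). The profile of a position correlated between biomes with a mean r across probes of 0.603 (0.393 to 0.809), as places on a slide may give. Different positions had a mean r of -0.195. The profiles of a biome are deviations from its own mean and cancel out, so that negative mean follows largely from the positive one. Single pairs of different positions overlapped the range for the same position. Position 3 in tropical and position 2 in boreal arrays had an r of 0.547. Probes whose IDs differ only in the final letter shared position deviations 0.0247 more than random pairs, within the spread of random pairs, so site types that repeat every 4 numbers stay open. Over all arrays too, such pairs were hardly more alike than random pairs (median r 0.151 against 0.121), so they could not decide this.

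The number of listed probes went with the lowest listed signal of an array (log2). That signal is the lowest among the listed probes themselves, and array totals lay within a narrow range. Some negative correlation is thus built in, and its size without a differing limit was not computed. The correlations below therefore do not by themselves show a signal limit that differs between arrays. In boreal arrays Pearson's r was -0.786 and Spearman's rho -0.821, and in temperate arrays r was -0.833 and rho -0.758 (permutation p = 1e-05 for each, the smallest possible; adjusted p = 1.5e-05 over 3 biomes; n = 40 each). In tropical arrays r was -0.307 (p = 0.0536, adjusted p = 0.0536) and rho -0.164 (p = 0.312). Without the 2 farthest arrays r was -0.788, -0.796 and -0.2196, and over means of runs -0.845, -0.872 and -0.310 (permutation p = 0.00202, 0.00151 and 0.391). Above 1 common signal -0.831% of the temperate minus boreal difference in listed probes was left, which is consistent with a low-signal limit that differs between arrays, although a true difference among weak probes would be lost there too and stays open.

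Among pairs of probes whose IDs differ only in the final letter and of which at least 1 differed between biomes, 137 of 222 (61.7%, exact 95% interval 54.97% to 68.14%) shared the sign of the log2 difference, against 51.8% for random partners. The pairs come from 3 comparisons that share arrays, which the interval does not allow for. The counts were 12 of 24 (50%) for tropical minus temperate, 31 of 48 (64.6%) for tropical minus boreal and 94 of 150 (62.7%) for temperate minus boreal. Of the bounds set beforehand for the pooled share, 65% for a difference in the soil community and 50% against it, neither was reached. The first comparison alone lies at 50%, with an exact interval of 29.1% to 70.9%. The 150 such pairs listed on all arrays had a median r of 0.151 over the arrays, against 0.121 for random pairs. Whether these pairs share a target is not stated in the sources used here. The share of signs therefore cannot decide on a difference in the soil community.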
